A study of Mus musculus with 10 samples.

How the data were processed

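Liver RNA was measured by bulk RNA sequencing in 10 mouse libraries, 6 from wild-type (WT) and 4 from Ifrd1 knockout (KO) mice, all taken 12 hours after partial hepatectomy. Per the labels' protocols, liver lobes (median and left lateral) were removed under isoflurane, RNA was extracted with TRIzol, mRNA was enriched on oligo(dT) beads, and libraries were made with a NEBNext Ultra kit and sequenced on an Illumina NovaSeq. The values used are raw read counts per gene symbol as the authors deposited them, with 1 column per library and no pooling. Per the submitters' processing notes, STAR, HTSeq and DESeq2 were used with the mouse build mm10; their versions, their roles, the gene annotation and the strand setting are not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical family members, may therefore have been divided or lost in ways the counts cannot show.

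The table held 23056 gene symbols with whole-number counts, of which 22 had no count in any library. Library totals lay between 12307446 and 17098012 counts. Every column was used (0 columns were left out). Groups and replicate numbers were taken from the sample labels. Every pair of libraries of a group differed far beyond sampling noise, with a chi-square per degree of freedom between 23.5 and 186, so no library was counted as a copy of another. The labels number the libraries but do not name the animal each came from. Each library was taken to be the liver of a different mouse, and p-values measure the spread between these libraries.

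The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM scaling, the filterByExpr filter by group, robust dispersion and no covariate, on all 10 libraries. It ran on 13688 genes, which held 99.8% of counts. P-values were adjusted by Benjamini-Hochberg and called under 0.05. The standard error (SE) of a log2 fold change was taken as its size over the square root of the F statistic. Normalised expression is given in CPM, counts scaled by the TMM-adjusted library size, as mean ± SD over 6 WT and 4 KO libraries. Log2 CPM used a prior count of 2. Single measures per library were compared with a two-sided exact permutation test over the 210 ways to choose 4 of 10 libraries, whose smallest p is 0.00476; genes were put on the log2(CPM + 0.5) scale for this test.

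The design, the tests, the gene lists and the rule for naming genes were fixed before the data were examined. Named genes were a panel of 10 (Ifrd1, Ifrd2, Myc, Ccnd1, Mki67, Clec4f, Adgre1, Ccl2, Cyp7a1, Alb), the 8 called genes with the largest fold change in each direction that had a mean of at least 1 CPM in the higher group and a gene name, and up to 3 called members of each list with the smallest p, 53 genes in all. Of these, 1 is not reported here. Other genes named in the text are said to have been chosen after their values were seen. Of 42 gene lists of pathways and cell types, 38 had at least 5 tested members and were tested with camera (limma 3.58.1) at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated per list and fry, which asks whether the members of a list move one way, were run beside it. Members were also tested with the adjustment over the list alone. A list score is the mean over tested members of log2 CPM minus the gene's mean over the 10 libraries.

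Gene coordinates are those of GENCODE M21 on GRCm38, the assembly of the mm10 build, in which 22277 of the symbols (96.6%) were found. On counts simulated for KO against WT with 200 changed genes among 13401 genes tested, the same code recovered 6% of 1.5-fold, 16% of 2-fold, 80% of 4-fold and 90% of 8-fold changes, and 4% of its calls were unchanged genes. A simulated 1.5-fold decrease of 1 list was called with both settings of camera, and 0 of the other lists were called at the preset correlation. The simulated libraries varied gene by gene and had no shared structure, unlike the WT libraries described in the report.

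The alternatives were RLE and upper-quartile scaling, no filter and a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom with and without sample weights, no robust prior, 1 surrogate variable (sva 3.50.0), a minimum change of 2-fold, replicate numbers as a block, and leaving out each library in turn. A covariate for the clock genes and limma-voom with a separate spread per group were added after the data had been seen.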

Results

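The transcriptome of regenerating liver was measured 12 hours after partial hepatectomy, a surgical removal of liver lobes after which the remaining hepatocytes leave quiescence. Poly(A) RNA was sequenced from 6 livers of WT mice and 4 livers of mice labelled as knockouts (KO) of Ifrd1, which encodes interferon-related developmental regulator 1, a transcriptional co-regulator. The stated aim was to learn what Ifrd1 does in the regenerative response, and the only contrast was genotype at this single time. Total counts were 13525600 on average in WT (range 12307446 to 14340623) and 14859500 in KO (12675838 to 17098012). No unoperated liver was analysed here, so the values below compare genotypes after surgery and give no change from the resting state.

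The targeted gene was measured first as a check of the labels. Ifrd1 (ENSMUSG00000001627.12, chromosome 12, 40201567 to 40248504, minus strand, protein coding) fell from 58.7 ± 15.6 CPM in WT to 19.5 ± 4.38 CPM in KO. The log2 fold change was -1.59 (SE 0.23, adjusted p = 0.0258 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), a 3.01-fold lower level. The KO libraries lay between 13.0 and 22.6 CPM and the WT libraries between 40.2 and 81.7 CPM, without overlap (two-sided exact permutation p = 0.00476, the smallest the design allows). Reads thus remained on the gene in every KO library. Gene-level counts cannot show whether they came from exons inside or outside the altered part, or from cells that kept the gene, since the labels do not say in which cells it was knocked out. Ifrd2, the related family member, was at 23.2 ± 4.34 CPM in WT and 27.8 ± 1.43 CPM in KO and did not pass the test (adjusted p = 0.298 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Y-linked transcripts such as Ddx3y (at least 32.3 CPM) were present in each library and Xist stayed at or below 0.863 CPM. By these transcripts the animals of both groups were male. The Ifrd1 call was lost without any 1 KO library (adjusted p from 0.0985 without KO replicate 4 to 0.132 without KO replicate 3, with 0.110 without KO replicate 1 and 0.105 without KO replicate 2) and without WT replicate 1 (0.0521) or WT replicate 5 (0.0648) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, while its log2 fold change stayed between -1.67 and -1.44 in these fits.

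**Figure D1:**
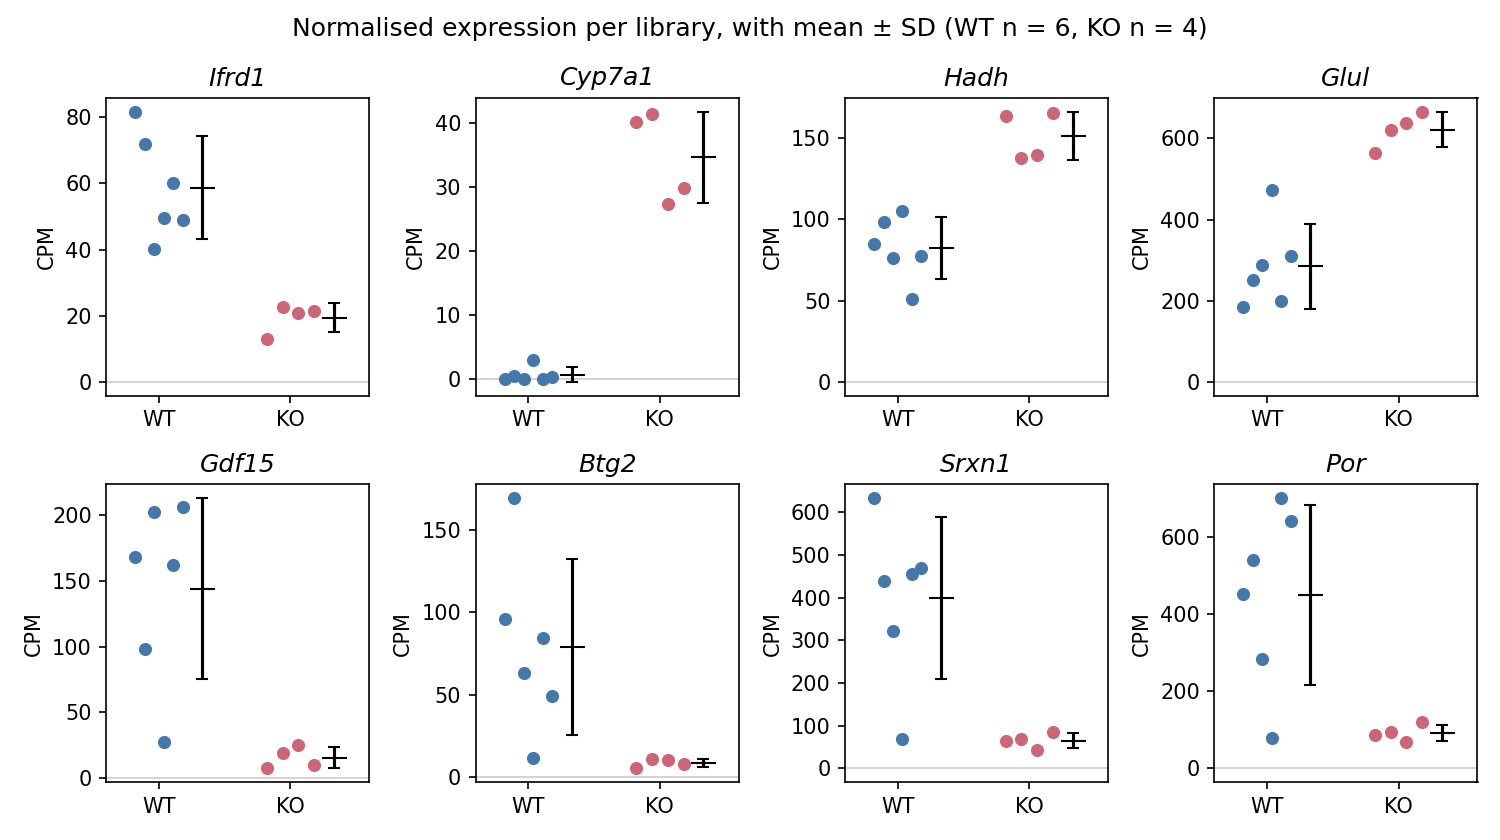
Normalised expression in CPM (y axes, linear) of 8 genes in each WT (blue, n = 6) and KO (red, n = 4) library, with the mean and SD beside the points. Ifrd1 lay between 13.0 and 22.6 CPM in KO and between 40.2 and 81.7 CPM in WT; Cyp7a1 reached at most 2.99 CPM in WT and at least 27.4 CPM in KO; the lowest WT points of Gdf15 (27.5 CPM) and Por (78.5 CPM) belong to WT replicate 4.

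The WT livers differed from each other far more than the KO livers did. On the first principal component of log2 CPM (48.6% of variance) the KO libraries lay close together, between 42.2 and 46.8, while the WT libraries spread from -79.3 to 40.1 (two-sided exact permutation p = 0.0143 for the difference of means, adjusted p = 0.143 over 10 library measures by Benjamini-Hochberg). WT replicate 4, at 40.1, lay beside the KO libraries and had a mean correlation of 0.970 with them against 0.918 with the other WT libraries, across genes. The biological coefficient of variation was 0.375 in WT and 0.182 in KO. WT replicates 5 and 6 stood apart on the second component (-44.0 and -47.1, against -0.412 to 39.5 in the other libraries). Mitochondrial transcripts took 21.5% ± 5.89 of counts in WT and 22.2% ± 6.03 in KO (exact permutation p = 0.862), and haemoglobin transcripts 0.0219% ± 0.00819 and 0.0219% ± 0.0113 (exact permutation p = 1). WT replicate 2 alone carried immunoglobulin transcripts at 0.0536% of counts, against at most 0.00205% elsewhere.

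**Figure D2:**
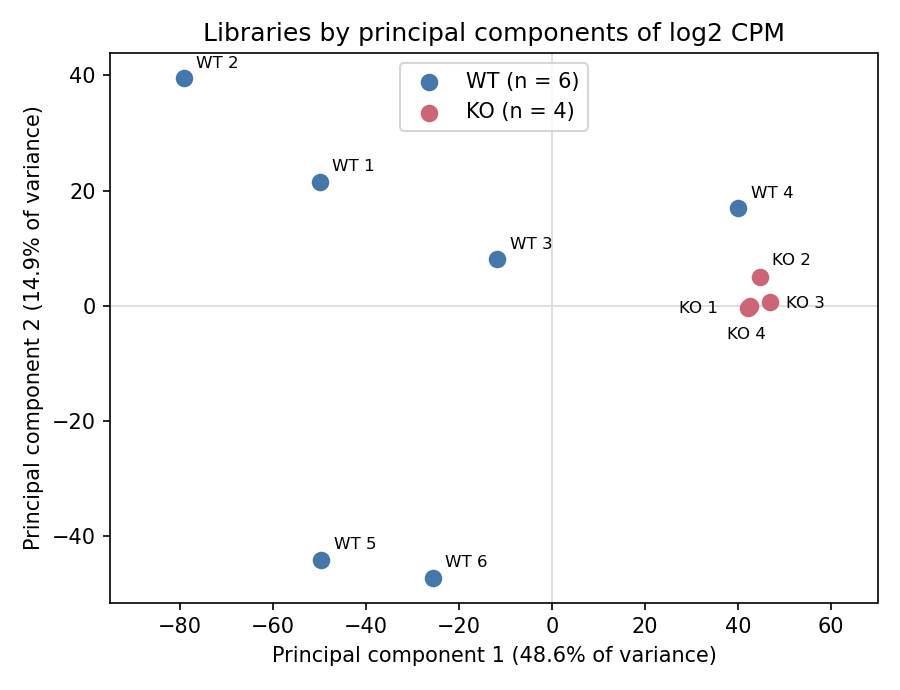
Positions of the 10 libraries on the first (x axis, 48.6% of variance) and second (y axis, 14.9%) principal components of log2 CPM, WT in blue (n = 6) and KO in red (n = 4). The KO libraries lie between 42.2 and 46.8 on the first component, WT replicate 4 lies beside them at 40.1, and the other WT libraries lie between -79.3 and -11.8.

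Across the transcriptome, KO livers had more Cyp7a1, the gene of the first enzyme of bile acid synthesis, and more transcript of 3 fatty acid oxidation enzymes (Eci1, Hadh and Acadm), and less Gdf15, Srxn1 and Btg2, genes known to respond to stress or growth stimuli. Of 13688 genes tested, 182 passed, 77 higher and 105 lower in KO, with adjusted p from 0.0221 upward in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Among them 51 rose and 81 fell at least 2-fold. The WT and KO libraries did not overlap in 152 of the 182 (83.5%) and in 945 of all 13688 tested genes (6.90%), where random labelings give 0.952%. The share among called genes is high in part because they were selected for a small p between the same groups. Of the 182, 24 had no gene name, and 18 of these were higher in KO. At an unadjusted p under 0.05 there were 3554 genes, 1587 higher and 1967 lower. The count depended on single libraries: it was 2893 without WT replicate 4, and 2, 55, 10, 2 and 20 without WT replicates 1, 2, 3, 5 and 6, and 0, 0, 0 and 2 without KO replicates 1, 2, 3 and 4, where 2729, 2681, 2740 and 2859 genes still had an unadjusted p under 0.05 in edgeR's quasi-likelihood test. DESeq2 on all libraries called 1624 genes, 579 higher and 1045 lower. Limma-voom called 318 and turned the balance, with 231 higher and 87 lower (72.6% higher, against 42.3% in edgeR). Each of the 182 genes kept its direction in every fit that measured it. WT replicate 4 lay closer to the KO mean than to the mean of the other WT libraries for 110 of the 182 genes (73 of those lower and 37 of those higher in KO).

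The largest increase was in Cyp7a1, the rate-limiting enzyme of bile acid synthesis (chromosome 4, 6265612 to 6275633, minus strand). It was nearly absent in WT, at 0.690 ± 1.15 CPM, and reached 34.7 ± 7.15 CPM in KO (log2 fold change 5.59, SE 0.72, adjusted p = 0.0221 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of 59 WT counts, 44 came from WT replicate 4 (2.99 CPM, the other WT libraries at most 0.529), and without that library the log2 fold change was 7.20. Among called genes with a gene name and a mean of at least 1 CPM in the higher group, the next largest increases were in Olfr1034 (4.88), Olfr1033 (4.58), Dclk3 (3.51), Platr4 (3.04), Adrb3 (2.81), P2rx3 (2.81) and Depp1 (2.62, from 3.93 ± 3.55 to 24.4 ± 9.89 CPM), all log2 fold changes. Olfr1033 and Olfr1034 are neighbouring olfactory receptor genes on chromosome 2 (86020633 to 86045171 and 86045861 to 86050742), and reads of related receptors could have been shared between them. P2rx3 also lies on chromosome 2 (84998583 to 85037462). Genes of this region were not counted separately, so a local difference between the groups was not tested there. Adrb3 encodes the beta-3 adrenergic receptor and P2rx3 an ATP-gated channel, both at low levels here (5.28 ± 1.46 and 1.47 ± 0.36 CPM in KO). None of these 8 overlapped between the groups. The log2 fold change of Platr4 was 3.64 without WT replicate 4, and that of Olfr1033 was 5.45 without WT replicate 6.

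By the same rule, the largest decreases among called genes were in Acot5, an acyl-CoA thioesterase (log2 fold change -7.13), Akr1b7, an aldo-keto reductase (-6.96), and Slc51b, a subunit of the basolateral bile acid transporter (-5.55, from 30.3 ± 16.5 to 0.651 ± 0.42 CPM). Hcar2, a hydroxycarboxylic acid receptor (-5.23), the neighbouring Gml (-5.22) and Gml2 (-5.17), the serine synthesis enzyme Psat1 (-4.32) and the efflux pump gene Abcb1a (-3.43) followed. Their adjusted p lay between 0.0418 and 0.0440 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The WT libraries were uneven in these genes, and WT replicate 4 had the lowest WT level of each. Acot5 was at 0.340 CPM in WT replicate 4 and 9.56 to 59.7 CPM in the other WT libraries. Slc51b was at 0.408 CPM against 28.4 to 48.3 CPM. The groups overlapped for Acot5, Slc51b, Hcar2, Psat1 and Abcb1a, in each case only through WT replicate 4. Without KO replicate 2 the log2 fold changes of Acot5 and Gml2 were -7.91 and -6.04. That of Gml was -5.92 without KO replicate 4, and that of Akr1b7 -6.23 without WT replicate 2. Acot5, Gml, Gml2 and Abcb1a have close relatives in the genome, so their counts are uncertain.

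The list of fatty acid oxidation and ketogenesis was higher in KO by camera at the preset correlation (adjusted p = 1.75e-06 by Benjamini-Hochberg). It did not pass with an estimated correlation (adjusted p = 0.769) or by fry (adjusted p = 0.0772). Of 30 members, 3 rose and 0 fell over all genes tested, and 16 rose and 1 fell adjusted over the list alone, with 26 of 30 fold changes above 0 (median log2 fold change 0.54). The 3 called members encode enzymes of mitochondrial beta-oxidation: Eci1 rose from 55.8 ± 15.6 to 113 ± 15.0 CPM (log2 fold change 1.01), Hadh from a mean of 82.1 to 151 CPM (0.88, SE 0.19) and Acadm from 168 ± 40.4 to 311 ± 61.8 CPM (0.89), each without overlap between the groups. The exact permutation test of the list score gave p = 0.0190, with adjusted p = 0.181 over 38 lists by Benjamini-Hochberg, and WT replicate 4 had a score of 0.20 among KO scores of mean 0.31 ± 0.26.

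The cholesterol synthesis and pericentral hepatocyte lists were also higher by camera at the preset correlation (adjusted p = 5.74e-04 and 0.0306 by Benjamini-Hochberg). Neither passed with an estimated correlation (adjusted p = 0.772 and 0.769). Of 23 cholesterol synthesis genes, 2 rose over all genes tested and 8 rose adjusted over the list alone, and none fell in either count. Sc5d rose from 57.8 ± 9.58 to 130 ± 62.6 CPM and Hsd17b7 from 44.0 ± 10.4 to 84.5 ± 24.1 CPM. KO replicate 2 had the highest level of Sc5d (224 CPM, the other KO libraries 96.0 to 100.3) and a list score of 1.26. The scores of KO replicates 1 and 4 (-0.29 and -0.15) lay within the WT range of -0.63 to 0.15. The exact permutation test of this score gave p = 0.129 (adjusted p = 0.330 over 38 lists by Benjamini-Hochberg), and camera gave adjusted p = 0.0841 without KO replicate 2. Of 22 genes marking hepatocytes around the central vein, 1 rose and 1 fell over all genes tested, against 3 and 1 adjusted over the list alone. Glul, glutamine synthetase, rose from 285 ± 105 to 622 ± 43.3 CPM, and Rhbg, an ammonium transporter, fell from 4.33 ± 1.32 to 1.14 ± 0.53 CPM. The camera call of this list was lost without WT replicate 1 (0.0680), WT replicate 5 (0.0515) or KO replicate 4 (0.0569). Of 20 periportal genes, 1 rose (Aldh1b1, log2 fold change 0.92) and 1 fell (Sds), and the list did not pass (camera adjusted p = 0.693 by Benjamini-Hochberg).

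The lists of ribosome biogenesis and of immediate early and priming genes were lower in KO by camera at the preset correlation (adjusted p = 4.29e-08 and 5.14e-05 by Benjamini-Hochberg). Neither passed with an estimated correlation (adjusted p = 0.769 for both). Of 30 ribosome biogenesis genes, 28 had fold changes below 0 (median log2 fold change -0.47), 1 fell over all genes tested and 19 fell adjusted over the list alone. Rrp12, a ribosome maturation factor, fell from 25.0 ± 7.13 to 11.8 ± 2.03 CPM, although WT replicate 4 lay within its KO range at 14.4 CPM. Fry gave this list adjusted p = 0.0411. Of 19 immediate early and priming genes, 17 had fold changes below 0, 1 fell over all genes and 8 fell adjusted over the list alone. Btg2, an antiproliferative early response gene, fell from 78.9 ± 53.5 to 8.31 ± 2.56 CPM. Myc was at 32.0 ± 13.0 CPM in WT and 14.9 ± 4.02 CPM in KO and did not pass over all genes (log2 fold change -1.10, adjusted p = 0.0855 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Fry gave the immediate early list adjusted p = 0.179, and camera with 1 surrogate variable gave it adjusted p = 0.505. WT replicate 4 had an immediate early score of -0.75, within the KO range of -1.19 to -0.21, and a ribosome biogenesis score of -0.14, against a KO mean of -0.26 ± 0.07.

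Of 4 stress response lists, 3 were lower in KO by camera at the preset correlation. None of these passed with an estimated correlation (adjusted p = 0.769 for each). In the list of p53 targets and cell cycle inhibitors, 2 of 16 tested genes fell over all genes and 6 fell adjusted over the list alone: Gdf15, a stress-induced cytokine, fell from 144 ± 69.0 to 15.7 ± 8.13 CPM (log2 fold change -3.20) and Sesn2 from 16.3 ± 8.60 to 3.93 ± 0.93 CPM. Camera gave adjusted p = 0.00173 by Benjamini-Hochberg, adjusted p = 0.769 with an estimated correlation, and fry gave adjusted p = 0.0411. In the NRF2 and oxidative stress list 2 of 20 fell and 0 rose over all genes, and 8 fell and 1 rose adjusted over the list alone: the peroxiredoxin-repair enzyme Srxn1 fell from 398 ± 190 to 65.1 ± 17.3 CPM and the metallothionein Mt2 from 1717 ± 907 to 435 ± 59.4 CPM. Camera gave adjusted p = 0.00422 by Benjamini-Hochberg, adjusted p = 0.769 with an estimated correlation and adjusted p = 0.570 with 1 surrogate variable. In the unfolded protein and integrated stress response list 2 of 26 fell over all genes (Psat1 and Sesn2) and 3 adjusted over the list alone, with camera adjusted p = 0.00917 by Benjamini-Hochberg, adjusted p = 0.769 with an estimated correlation and adjusted p = 0.150 with 1 surrogate variable. The score of this list was 0.87 and 0.62 in WT replicates 1 and 2 and between -0.18 and 0.04 in the other WT libraries. The KO libraries lay between -0.46 and -0.25. Psat1 acts in serine synthesis and Sesn2 in nutrient sensing, and neither is a chaperone. Of 14 heat shock genes, 1 fell (Bag3, a co-chaperone, from 66.6 ± 10.7 to 35.1 ± 5.59 CPM), and that list did not pass (camera adjusted p = 0.483 by Benjamini-Hochberg). WT replicate 4 had an NRF2 score of -0.41, equal to the KO mean of -0.41 ± 0.08. Its Srxn1 level of 68.1 CPM lay within the KO range.

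**Figure D3:**
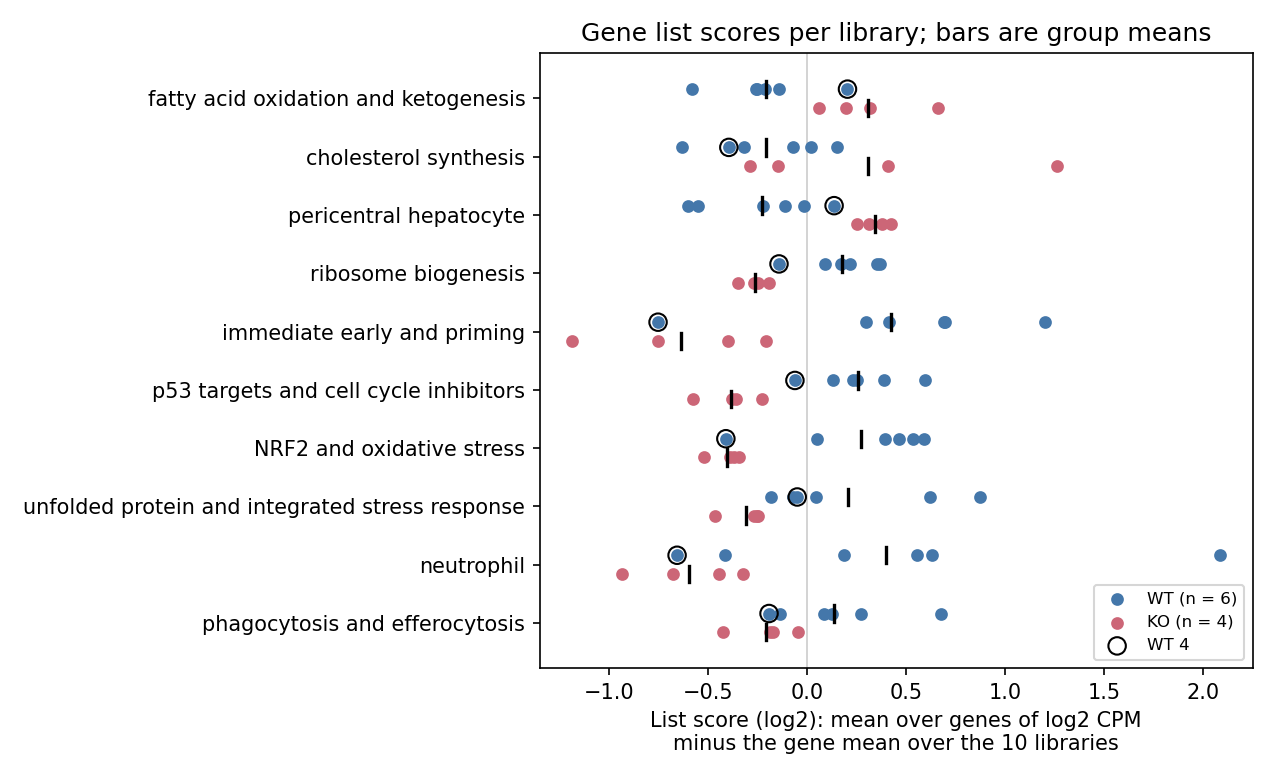
List scores (x axis, log2: mean over member genes of log2 CPM minus the gene's mean over the 10 libraries) of the 10 lists past the camera threshold, for each WT (blue, n = 6) and KO (red, n = 4) library, with bars at group means and WT replicate 4 circled. The KO libraries lie to the right of the WT mean in the lists of fatty acid oxidation and pericentral genes and to the left of it in the lower 7 lists, and WT replicate 4 has an immediate early score of -0.75.

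Genes of amino acid, sugar and drug metabolism changed singly, while their lists did not pass the test. Of 29 genes of the urea cycle and amino acid catabolism, 2 fell and 1 rose over all genes tested, and 8 fell and 1 rose adjusted over the list alone. Tat, tyrosine aminotransferase, fell from 3065 ± 1067 to 1035 ± 322 CPM, and Sds, serine dehydratase, from 199 ± 135 to 38.2 ± 10.8 CPM. Pgd of the pentose phosphate pathway fell from 61.3 ± 19.3 to 28.9 ± 2.23 CPM, and its list did not pass. Camera gave this list adjusted p = 0.0566 by Benjamini-Hochberg at the preset correlation and 0.769 with an estimated correlation, and fry gave adjusted p = 0.238. Por, the electron donor of microsomal cytochromes P450, fell from 450 ± 234 to 92.4 ± 21.3 CPM. WT replicate 4 lay within the KO range for Tat (1366 CPM), Pgd (30.4 CPM) and Por (78.5 CPM), so the groups overlapped for these genes. They did not overlap for Sds. In the bile acid list of 25 tested genes Cyp7a1 rose and Slc51b fell, 2 rose and 3 fell adjusted over the list alone, and the list did not pass (camera adjusted p = 0.887 by Benjamini-Hochberg). The sex-biased steroid enzymes Hsd3b5 (1.43 ± 1.08 to 7.73 ± 2.34 CPM) and Cyp17a1 (7.63 ± 3.33 to 21.1 ± 5.75 CPM) rose, but neither list they belong to passed. Of 19 male-biased genes, 10 had fold changes below 0, and 1 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.322 by Benjamini-Hochberg). Of 8 female-biased genes, 6 had fold changes below 0, and 1 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.657 by Benjamini-Hochberg). The scores of both lists varied widely in WT. Male-biased scores ran from -1.85 to 0.70 in WT and from 0.12 to 0.37 in KO. Female-biased scores ran from -1.06 to 1.48 in WT and from -0.61 to -0.20 in KO. Alb was at 32404 ± 14418 CPM in WT and 28821 ± 3354 CPM in KO and did not pass.

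Proliferation genes gave few calls at this time. In the list of G1 progression and S phase entry 1 of 25 tested genes fell, Ccne1, which encodes cyclin E1 (4.86 ± 2.17 to 1.14 ± 0.21 CPM), in both adjustments, and the list did not pass (camera adjusted p = 0.246 by Benjamini-Hochberg). Only 8 of 25 mitosis genes were high enough to test and 0 passed; Mki67 was at 1.02 ± 0.62 CPM in WT and 0.726 ± 0.37 CPM in KO, with 80 counts in all WT and 41 in all KO libraries, so a difference would be hard to detect at this depth. Ccnd1 was at 18.3 ± 15.3 and 16.2 ± 4.64 CPM (log2 fold change -0.17, SE 0.49). Among 26 mitogens and growth regulators 2 fell, against 4 lower and 1 higher adjusted over the list alone. The 2 were the EGF receptor ligand Hbegf (5.99 ± 3.44 to 0.616 ± 0.20 CPM) and the activin antagonist Fst (8.94 ± 4.66 to 1.87 ± 0.28 CPM). WT replicate 4 lay within the KO range for Ccne1 (1.02 CPM) and Hbegf (0.408 CPM), so the groups overlapped for these genes. They did not overlap for Fst.

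Macrophage and neutrophil markers were uneven among WT livers, and no member of either list passed over all genes. Of 10 tested neutrophil genes, 10 had fold changes below 0 and 5 fell adjusted over the list alone (median log2 fold change -2.04); camera gave adjusted p = 0.0198 by Benjamini-Hochberg and adjusted p = 0.769 with an estimated correlation. Without WT replicate 2 the median was -0.85, but that fit had no filter on low counts and took in list members not tested above. The 20 tested Kupffer cell genes had a median log2 fold change of -0.80, with 14 below 0, and did not pass (camera adjusted p = 0.0976 by Benjamini-Hochberg). In the same unfiltered fit without WT replicate 2 the Kupffer median was -0.32, again with members not tested above. Over the same 30 tested genes of both lists, the median moved from -0.94 with all libraries to -0.46 without WT replicate 2. Clec4f, a marker of resident macrophages, was at 43.1 ± 33.8 CPM in WT, with 107 CPM in WT replicate 2, and 15.9 ± 6.15 CPM in KO (log2 fold change -1.44, SE 0.55, adjusted p = 0.136 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Adgre1 (1.15 ± 0.64 and 0.820 ± 0.39 CPM) and the chemokine gene Ccl2 (1.59 ± 0.97 and 1.85 ± 0.59 CPM) did not pass. In the list of phagocytosis and efferocytosis 1 of 28 genes fell over all genes, the integrin gene Itgb3 (9.67 ± 4.03 to 3.48 ± 0.63 CPM), while 6 fell and 1 rose adjusted over the list alone; camera gave adjusted p = 0.0246 by Benjamini-Hochberg, adjusted p = 0.772 with an estimated correlation and adjusted p = 0.0841 without KO replicate 2. Fcgr2b of the sinusoidal endothelium rose (12.9 ± 2.53 to 26.2 ± 7.57 CPM), and its list did not pass (camera adjusted p = 0.242 by Benjamini-Hochberg). The interferon regulator Irf7 fell (24.0 ± 5.31 to 13.0 ± 1.65 CPM), and its list did not pass (camera adjusted p = 0.441 by Benjamini-Hochberg).

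Over all lists, 3 of the 38 tested were higher and 7 lower in KO by camera at the preset correlation, 0 with an estimated correlation, where the smallest unadjusted p was 0.0250, and 2 by fry (ribosome biogenesis, and p53 targets and cell cycle inhibitors). Splits of the 10 libraries that ignored genotype often gave as many: 79 of 100 drawn splits gave at least 3 lists higher and 31 gave at least 7 lower, the real split included. The smallest adjusted p of the exact permutation tests of the 38 list scores was 0.181 by Benjamini-Hochberg. Fry's test for change in either direction passed for 28 lists. The 28 lists that did not pass camera had adjusted p between 0.0566 and 0.982, and 15 of them held at least 1 called gene. In 8 lists, 0 of them past the threshold, the median, the mean and the test differed in sign.

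A knockout can carry flanking DNA of the strain it was made in, so genes near Ifrd1 were counted separately. Of 31 tested genes within 10 Mb of Ifrd1 on chromosome 12, other than Ifrd1 itself, 1 was called, against 177 of 13340 elsewhere (two-sided Fisher exact p = 0.340, odds ratio 2.48, 95% interval 0.0604 to 15.1). The called neighbour was Nampt (chromosome 12, 32819545 to 32853349), which encodes an enzyme of NAD synthesis and fell by 1.56 on the log2 scale (SE 0.32). Nampt was named after its values were seen. Its level in WT replicate 4 was 27.8 CPM, within the KO range of 23.4 to 33.2 CPM. Ifrd1 in that library was at 49.6 CPM, above every KO library.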

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

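The tests of WT replicate 4 (except sequencing depth), of the clock genes and of the macrophage markers were chosen after the values they use had been seen; the test of sequencing depth and the counts over other splits of the libraries were set before their results. A library far from the others of its group was found in 8 of 154 groups of values, and chance alone gives about 7.7. WT replicate 2 stood apart in Clec4f (107 CPM, the others 10.2 to 45.1), Alb (59959 CPM, the others 19180 to 32635), Hilpda (355 CPM, the others 6.94 to 94.8) and immunoglobulin transcripts (0.0536% of counts, the others at most 0.00205%). WT replicate 4 stood apart in Cyp7a1 (2.99 CPM, the other WT libraries 0.0661 to 0.529), still below the lowest KO library at 27.4 CPM. KO replicate 2 stood apart in Alb (33821 CPM, the other KO libraries 26698 to 27605) and Sc5d (224 CPM, the others 96.0 to 100.3). KO replicate 3 had the lowest unfolded protein and integrated stress response score (-0.46, the other KO libraries -0.27 to -0.25).

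Chance is argued against as the source of the gene counts but not excluded, since only 100 of the 210 possible splits were drawn. Among these splits of the 10 libraries into 6 and 4, only the real 1 gave as many as 77 genes higher (highest other 27). Only the real 1 gave as many as 105 lower (highest other 30). Of the 99 other splits, 98 gave 0 calls in edgeR's quasi-likelihood test. The remaining split gave 57 and set WT replicates 1, 2, 3 and 6 against the other libraries. The other splits that set 4 WT libraries without WT replicate 4 against the rest were not drawn. Their counts are not known. For the gene lists chance cannot be excluded either. At least 3 lists higher came from 79 of the 100 splits (real value 3, highest other 15), and at least 7 lists lower from 31 (real value 7, highest other 16), so shared variation among the livers gives list calls at the preset correlation without regard to genotype.

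WT replicate 4 lay beside the KO libraries on the main axis of variation. A KO liver carrying a WT label is argued against by its Ifrd1 level of 49.6 CPM, within the range of the other WT libraries (40.2 to 81.7) and above every KO library (at most 22.6). Sequencing depth differed little between libraries (12307446 to 17098012 counts, 14340623 in WT replicate 4), so thinning could hardly move this library. With every library thinned to 12307446 counts, WT replicate 4 stayed at 0.0453 of the way from the KO mean to the mean of the other WT libraries, against 0.0456 before. Its position was thus the same at equal depth. A lower share of all non-parenchymal cells is argued against as the whole source. Such a change can lower no gene by more than markers found only in those cells. Against the other WT libraries, the 105 genes called lower had a median of -1.12 log2 units and 64 Kupffer, endothelial and stellate markers -0.14. The difference was -0.98 (SD 0.38 among the other WT libraries, -0.32 to 0.60), and Srxn1 was at 68.1 CPM against 322 to 634 CPM. By list score the markers differed by -0.59 (Kupffer), -0.10 (endothelial) and 0.055 (stellate). The 105 genes were selected from these same libraries. Expression of the markers in hepatocytes would lessen their fall and was not measured. A weaker response to surgery in that animal, or a different surgical or sampling condition, may also give this position and was not tested.

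WT replicates 5 and 6 stood apart in clock transcripts: Npas2 was at 0.173 and 0.0773 CPM, against 4.84 to 13.1 CPM in the other 8 libraries, and Per3 at 7.08 and 16.5 CPM, against 1.09 to 5.70 CPM. The evening minus morning clock score, over 8 and 5 genes of the clock list, was 1.41 and 2.18 log2 units in these libraries and -0.96 to 0.08 in the others, with the evening genes higher and the morning genes lower, which is consistent with surgery or collection at a different time of day. Membership in the general spread of the WT livers cannot be told apart from this, since both libraries also stood apart on the second principal component made without 18 clock genes (-43.9 and -46.8, against -0.48 to 39.4 in the other 8). The clock shift is argued against as the whole source of the genotype calls: without WT replicates 5 and 6 the log2 fold changes of the called genes were a median 0.965 of their values with all libraries, and 177 of 177 kept their sign, although 4 genes were called with these 8 libraries. Feeding and a second surgical session were not tested.

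Kupffer and neutrophil markers had a median log2 fold change of -0.94 in KO against WT over 30 genes, none of which passed over all genes tested in edgeR's quasi-likelihood test, while 5, all neutrophil genes, fell adjusted over the list alone. The Kupffer list did not pass (camera adjusted p = 0.0976 by Benjamini-Hochberg), and the neutrophil list passed at the preset correlation (0.0198) but not with an estimated one (adjusted p = 0.769). WT replicate 2 alone as the source cannot be told apart from a genotype difference, since without it the median was -0.46, about midway between its full value and 0. A lower share of all non-parenchymal cells also cannot be told apart: the 44 endothelial and stellate genes had a median of 0.09, higher by 1.02 (95% bootstrap interval over genes 0.62 to 1.26), but over the libraries the score difference had a two-sided exact permutation p of 0.0524. Genotype, through fewer resident or recruited phagocytes or lower expression in them, may account for the pattern as well and stays open.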

How the results depend on the processing

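The direction of the calls was stable across settings, while their significance was not, and their size shrank with 1 surrogate variable to a median 0.604 of the log2 fold changes in the report (Akr1b7 -2.45 from -6.96, Psat1 -1.17 from -4.32, Btg2 -0.96 from -3.25). Each of the 182 called genes kept its sign in all 24 alternatives that measured it, but 0 of 46 called named genes passed in all of theirs, and a called named gene passed in a median of 10 of 23; 24 sign changes, counted gene by setting, fell on named genes that did not pass. Clock covariate and separate spread were added after seeing the data. Numbers of genes higher and lower were 77 and 105 in the report, 579 and 1045 with DESeq2, 231 and 87 with limma-voom, 1406 and 1223 with sample weights, 924 and 776 with a separate spread per group, 0 and 0 with 1 surrogate variable (539 genes at unadjusted p under 0.05), 51 and 81 at a minimum of 2-fold, 7 and 5 with the clock covariate, and 3 and 1 with numbers 1 to 4 of both groups. Without 1 library at a time they ranged from 0 (without KO replicates 1, 2 and 3) to 1420 and 1473 (without WT replicate 4). With the replicate number as a block they were 0 and 0 (2860 genes at unadjusted p under 0.05). Whether the numbers pair the libraries is not known. Same-number correlations were -0.03 to 0.18 (mean 0.050, against -0.009 for other numbers), and 2 of 4 KO libraries correlated best with their own number. These values do not settle it. RLE, upper-quartile scaling, no robust prior, and the other filters moved the total to between 153 and 233. Ifrd1 passed in 14 of 23 alternatives; its log2 fold change was -1.17 with the surrogate variable, -1.61 with the replicate block and -1.65 with numbers 1 to 4, none of which passed, and -1.68 to -1.44 over the fits without 1 library. Lists higher and lower were 3 and 7 in the report, 0 and 0 with an estimated correlation and 0 and 2 with fry, and 6 and 5 with the surrogate variable. With that variable the lists of immediate early genes (adjusted p = 0.505), NRF2 (0.570) and unfolded protein and integrated stress response (0.150) were no longer called. It also turned the direction of lists of phagocytosis (adjusted p = 0.505, higher), neutrophil (0.135, higher), fatty acid and triglyceride synthesis (0.0315, higher) and male-biased genes (8.69e-04, lower). The neutrophil call was also lost with the stricter filter (0.0689) and with numbers 1 to 4 (0.0985), and the phagocytosis call with the clock covariate (0.102). Fewer libraries may account for part of the losses without 1 library, but this was not tested, and leaving out WT replicate 4 raised the number of calls. The cause of the other changes was not tested either. In simulated counts 16% of 2-fold changes were recovered at this depth and number of libraries. Those simulated counts had no variation shared between genes.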

Other observations

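The tests below were chosen after the data had been seen, and the genes named here lie outside the rule unless the report names them. Lipid storage and uptake genes moved in both directions: of 24 tested genes of lipid droplets, uptake and lipolysis, 0 passed over all genes, while 5 rose and 5 fell adjusted over the list alone. Hilpda, which encodes an inhibitor of lipolysis on lipid droplets, fell adjusted over the list alone, from 95.9 ± 132 CPM in WT, where it ranged from 6.94 to 355 CPM, to 6.77 ± 1.40 CPM in KO (log2 fold change -3.82, and -2.71 without WT replicate 2). Cd36, which encodes a fatty acid transporter, rose adjusted over the list alone, from 14.8 ± 6.93 to 30.3 ± 13.2 CPM. Among pericentral genes, the Wnt target Lgr5 rose adjusted over the list alone, from 0.756 ± 0.83 to 5.55 ± 1.94 CPM (log2 fold change 2.84, SE 0.67), with no overlap between 6 WT and 4 KO libraries; over all genes its adjusted p was 0.0546 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and without WT replicate 4 it was 0.00319 (log2 fold change 3.49).

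Higher Cyp7a1 and lower Slc51b raised the hypothesis of lower bile acid signalling through the nuclear receptor FXR in KO. Over 9 other tested FXR-induced genes, 6 had fold changes below 0, 3 had fold changes above 0 and 0 passed (median log2 fold change -0.18). The mean score was lower in KO by a difference of -0.42 log2 units (two-sided exact permutation p = 0.105), which leaves the hypothesis open. WT replicate 4 had a score of -0.48, within the KO range of -0.67 to 0.08. Nr0b2, the FXR-induced repressor of Cyp7a1, was at 48.4 ± 24.4 CPM in WT and 8.40 ± 7.85 CPM in KO (log2 fold change -2.54, adjusted p = 0.0860 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its KO levels ran from 1.21 to 19.1 CPM, the highest in KO replicate 3, and WT replicate 4 lay within them at 5.58 CPM.

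Lower Por, Abcb1a and Akr1b7 raised the hypothesis of lower activity of the xenobiotic receptors CAR and PXR in KO. Over 18 other genes they induce, 16 had fold changes below 0 and 0 passed, with a score difference of -0.93 log2 units (two-sided exact permutation p = 0.0619, 0.105 after Benjamini-Hochberg adjustment over both hypotheses), so this also stays open. Cyp2b10, the usual CAR marker, was at 11.7 ± 10.3 CPM in WT and 1.16 ± 0.63 CPM in KO (log2 fold change -3.30, adjusted p = 0.0535 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). WT replicate 4 had the lowest score of all 10 libraries (-0.91, KO libraries -0.68 to -0.33), so genotype does not separate the scores.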
